A study of Homo sapiens with 14 samples.

How the data were processed

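The samples were bone marrow from 8 patient-derived xenograft models of paediatric AML, with 6 libraries after cytarabine and 8 after saline. Per the labels' protocols, total RNA was extracted with a column kit that removes genomic DNA, and 150 bp paired-end mRNA libraries were sequenced on an Illumina NovaSeq with 25M reads planned per sample. The deposited table holds estimated counts per gene and library, with no normalization. RSEM 1.30 and Bowtie2 2.10 are named in the submitters' processing notes, along with the builds GRCh38 and hg19. Which tool aligned and which counted, which build each library used and how mouse reads were treated are not given in the sources used here, so no coordinates are printed. The 12 libraries of models 1 to 6 hold whole numbers. In those of models 7 and 8, 30.0% and 35.1% of the values have decimals, and these libraries correlate with the 12 at 0.593 to 0.861 and with each other at 0.902.

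The table has 19201 entries. Left out were 2 entries whose names had turned into dates, with 0.00546% of the counts, and 45 sex-linked genes. Of the symbols 18780 matched the RefSeq gene table and 409 an older symbol. Values were rounded to whole numbers. Groups came from the treatment label and pairs from the model label. Model 7 and model 8 have no treated partner and entered only the saline values, the 14-library alternatives and the comparison of genes listed at 0. The labels give 1 library per model and treatment and name no separate animals. The p-values of the gene tests and of the sign-flip test therefore measure the spread between models. Pairing came from the labels, which give both libraries of a pair the same model and so the same donor. Deviations of the 2 libraries of a model from their group means correlated at 0.941, 0.739, 0.863, 0.925, 0.930 and 0.952 for models 1 to 6.

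Genes were kept by filterByExpr over the treatment groups, with a minimum count of 10 and a minimum total of 15, which left 12020. The main test was edgeR 4.0.16 (R 4.3.3) with TMM factors, a robust quasi-likelihood fit with the model as a block, and Benjamini-Hochberg adjustment at 0.05. Log2 fold changes are cytarabine over saline, with SE from that fit. CPM and per-model differences in log2(CPM + 1) used the same factors, while saline levels over models used factors computed over the 14 libraries. Library totals of 20535000 to 32316300 counts set the precision of low genes.

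Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and adjusted over the 30 lists tested. Beside it stood camera with an estimated correlation, fry, and an exact two-sided sign-flip test over 64 patterns of the per-model differences in list mean. Camera sets the members of a list against the other genes, so its p-values at the preset correlation do not measure the spread between models. The correlations estimated for the lists ran from -0.0671 to 0.832. The 31 lists covered cytarabine transport and metabolism, drug efflux, the leukaemia stem cell score, stem and progenitor, HOX and MEIS, granule, monocyte and macrophage, MHC class II, erythroid, megakaryocyte, T and NK, B and plasma, and stromal and endothelial genes. They also covered S phase, G2/M phase, p53 targets, DNA repair, the BCL2 family, oxidative phosphorylation, fatty acid oxidation, glycolysis, cholesterol synthesis, MYC-driven ribosome biogenesis, NF-kB, interferon, immediate early, unfolded protein response, adhesion, AML surface antigens, ribosomal proteins and mitochondrially encoded genes. Similarity of libraries was tested by exact permutation over 720 pairings, one-sided.

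The genes named follow a rule. It takes the genes past the threshold with the largest changes or, as here where none passed, the 8 with the smallest p in each direction. It adds 16 genes of cytarabine handling and AML biology and up to 3 members of each list with the smallest p. Members of the MHC class II list are given as a list only, and some genes the rule names are not reported here. Design, lists, naming rule and alternatives were fixed before the data were examined, apart from 1 alternative chosen after seeing the data, filterByExpr with the paired design. The other alternatives were RLE and upper-quartile factors, library size alone, DESeq2 1.42.0, limma-voom, other filters and thresholds, no block, the 14 libraries, other pseudocounts and leaving out each model. Transcript lengths and overlaps between genes came from GENCODE v29, used for names and lengths alone.

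The gene test was tested on simulated counts for 11831 genes. It recovered 65 of 99 genes changed by a log2 of 1 (65.7%) and 89 of 96 changed by a log2 of 2 (92.7%), with 7 false calls. In the simulated list test a p53 list shifted by 0.5 was recovered, and 1 of the other lists was called. Some of the other lists share genes with the p53 list, so that call need not be false. Each simulated gene was drawn independently, whereas the correlations estimated within the real lists reached 0.832. The simulated recovery and false calls therefore do not carry over to genes that vary together. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.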

Results

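Bulk RNA sequencing was carried out on bone marrow from patient-derived xenografts of paediatric acute myeloid leukaemia (AML), in which human leukaemia cells grow in mice. The 14 libraries came from 8 xenograft models. Models 1 to 6 each gave 1 library after cytarabine (AraC) and 1 after saline, and models 7 and 8 gave a saline library alone. Cytarabine is a nucleoside analogue that blocks DNA synthesis and a mainstay of AML chemotherapy. The series text speaks of diagnosis and relapse samples, whereas the sample labels give the treatment, which is the contrast used here. Estimated counts per gene summed to between 20535000 and 32316300 per library, and to at least 23025900 in each of the 12 paired libraries. In those 12 libraries 3363 genes were listed at 0. Among them were 7 ribosomal protein genes and IL3RA, the interleukin-3 receptor alpha chain, which had over 100 counts in both libraries of models 7 and 8. A value of 0 in the paired libraries was therefore not read as absence of a transcript.

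The first comparison asked whether the xenograft model or the treatment ordered the libraries. The model did so far more strongly. Over the 12020 genes tested, a cytarabine library correlated with the saline library of its own model with a mean Pearson r of 0.979, ranging from 0.950 in model 2 to 0.995 in model 6. With the saline libraries of other models the mean was 0.818, and the highest value was 0.955. An exact one-sided permutation test over the 720 pairings gave p = 0.00139 (n = 6 pairs), the smallest value this design can give. Among the 6 libraries of the other treatment, each of the 12 paired libraries had its best match in its own partner. Libraries of the same treatment were not candidates in this count. The model accounted for 93.5% of the sum of squares of log2(CPM + 1), and the treatment for 1.74%. These correlations run across genes, which are not independent replicates.

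**Figure D1:**
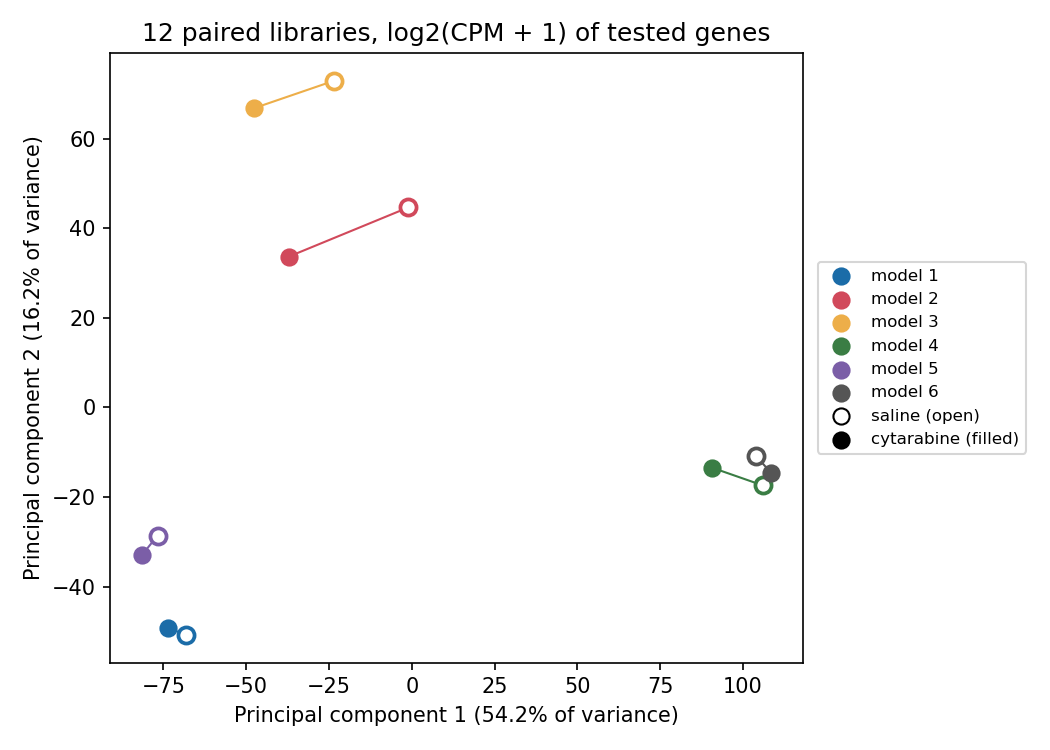
The 12 paired libraries on the first 2 principal components of log2(CPM + 1), which hold 54.2% and 16.2% of the variance, with open circles for saline, filled circles for cytarabine and a line joining the libraries of each model. In models 1, 3 and 5 each library lies nearest its own partner. The libraries of models 4 and 6 lie among each other, and each library of model 2 lies about as near to a library of model 3 as to its partner. The longest lines belong to models 2 and 3.

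Saline libraries differed widely between models. CD34, a surface marker of stem and progenitor cells, averaged 1236 ± 1492 CPM (SD, n = 6) in models 1 to 6 and ranged from 10.1 to 3622 CPM. CD33, a myeloid surface antigen, averaged 192 ± 104 CPM with a range of 91.8 to 341. DCK, the kinase that activates cytarabine, averaged 102 ± 40.0 CPM and ranged from 63.3 to 178. SAMHD1, which hydrolyses the active triphosphate of cytarabine, averaged 78.9 ± 106 CPM and ranged from 2.66 to 284. The mean log2(CPM + 1) of the monocyte and macrophage genes ran from 1.42 to 7.49 over these saline libraries (SD 2.42). That SD is 2.47 times the mean cytarabine difference of the list. For the p53 target genes the saline SD was 0.26, against a mean cytarabine difference of 0.28.

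The main comparison asked which genes differed between cytarabine and saline within a model. The genes with the smallest p on the higher side included CDKN1A, which encodes the cell cycle inhibitor p21, the histone variant gene H2AJ and the p53-responsive kinase gene PLK2. On the lower side stood MMP2, a matrix metalloproteinase gene, IGLL1, which encodes part of the surrogate light chain, and GFRA2, a receptor gene of the GDNF family. CDKN1A averaged 203 ± 83.0 CPM after saline and 422 ± 213 CPM after cytarabine (SD, n = 6), with a log2 fold change of 0.92 ± 0.21 (SE), and was higher in 5 of 6 models. None of these differences passed the planned test.

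The edgeR quasi-likelihood test with the model as a block found 0 of 12020 genes past an adjusted p of 0.05, the smallest adjusted p being 0.558. At an unadjusted p under 0.05 it counted 918 genes, 473 higher and 445 lower, where 601 are expected by chance. That unadjusted count was 371 without model 2, 341 without model 3, 1385 without model 5 and 1488 without model 6. The count past the adjusted threshold was 0 with limma-voom and 5 with the DESeq2 Wald test. The 5 genes were CDKN1A and H2AJ on the higher side (DESeq2 adjusted p = 0.0376 and 0.0476) and MMP2, IGLL1 and GFRA2 on the lower side (0.0125, 0.0350 and 0.0376). H2AJ had a log2 fold change of 0.73 ± 0.15 (SE) and was higher in 6 of 6 models. The log2 fold changes of MMP2, IGLL1 and GFRA2 were -0.97 ± 0.18, -1.15 ± 0.23 and -1.32 ± 0.27 (SE), each lower in 6 of 6 models, though in model 1 IGLL1 (0.0745 and 0 CPM) and GFRA2 (0.149 and 0.0819 CPM) had under 10 counts in both libraries. In single models the distance between the pair varied: 1574 genes in model 2, 901 in model 3 and 455 in model 4 lay at least 2-fold apart, against 154 in model 5, 137 in model 1 and 49 in model 6. Genes with the same sign in 6 of 6 models numbered 235 higher and 253 lower, together 4.06% of those tested, where 3.125% would share a sign by chance. Of these 488 genes 38 had under 10 counts in both libraries of at least 1 model.

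**Figure D2:**
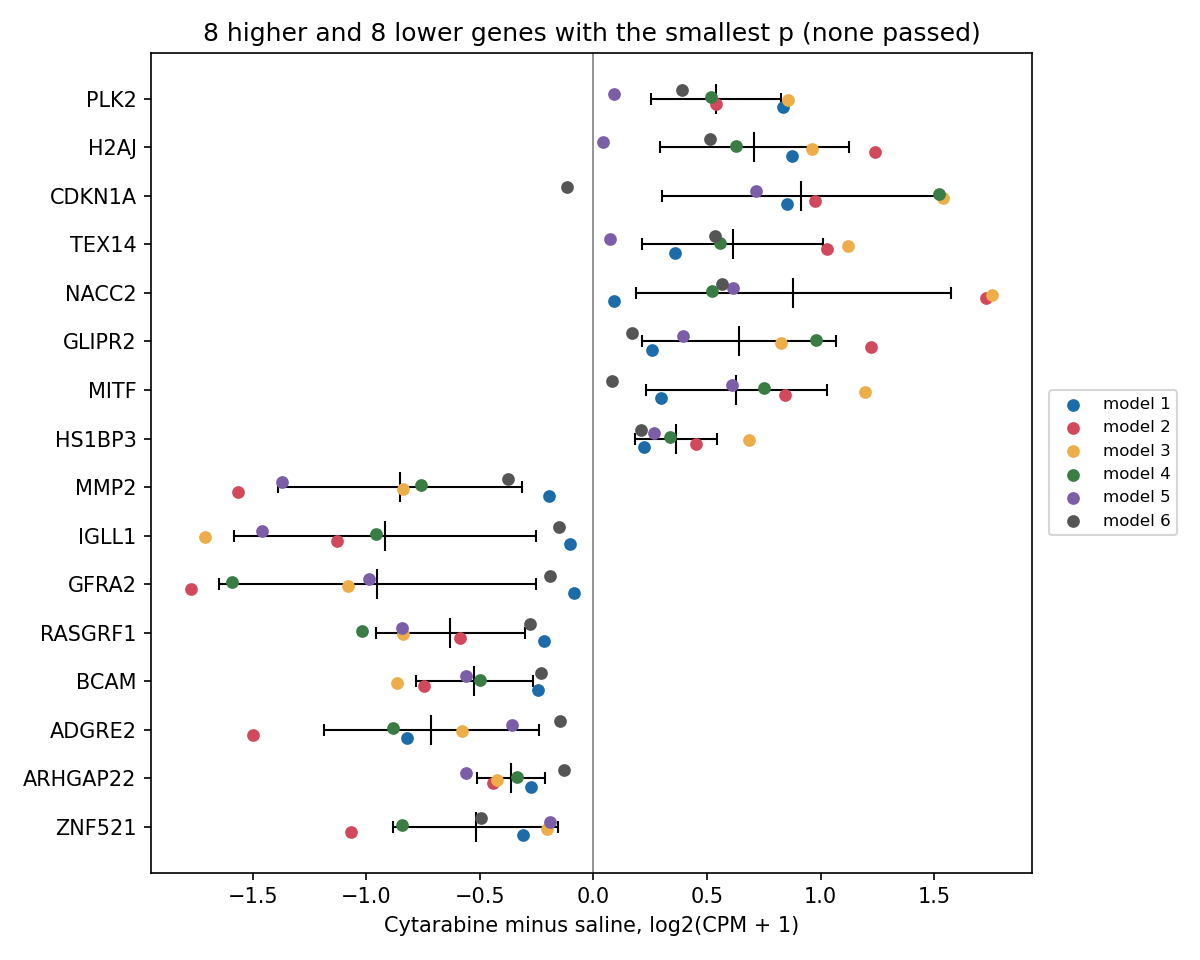
Cytarabine minus saline difference in log2(CPM + 1) for the 8 higher and 8 lower genes with the smallest p, with a coloured point for each of 6 models and the mean with SD in black. CDKN1A lies above 0 in 5 of 6 models and H2AJ in 6 of 6, while MMP2, IGLL1 and GFRA2 lie below 0 in 6 of 6, and no gene passed the edgeR test.

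Further genes from both ends of the ranking moved in the same direction in 6 of 6 models without passing the edgeR test (adjusted p = 0.558 for each). On the higher side PLK2 had a log2 fold change of 0.57 ± 0.12 (SE), GLIPR2 of 0.70 ± 0.18, TEX14 of 0.77 ± 0.20, HS1BP3 of 0.37 ± 0.10, the transcriptional repressor gene NACC2 of 1.18 ± 0.30 and the transcription factor gene MITF, with under 10 counts in both libraries of model 6, of 0.92 ± 0.24. On the lower side the Ras exchange factor gene RASGRF1 had -1.13 ± 0.24, the laminin receptor gene BCAM -0.57 ± 0.13, the myeloid adhesion receptor gene ADGRE2 -0.73 ± 0.16, the GTPase-activating protein gene ARHGAP22 -0.38 ± 0.09 and the zinc finger gene ZNF521 -0.56 ± 0.14.

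At the level of gene lists, 12 of the 30 lists tested passed camera with its preset correlation, 8 higher and 4 lower after cytarabine. With a correlation estimated for each list 0 lists passed, with adjusted p between 0.549 and 0.830 for these 12. Without the model as a block 7 lists passed; the stem cell score and cholesterol synthesis genes (both 0.0521), stem and progenitor cell genes (0.305), granule genes (0.254) and MHC class II genes (0.398) did not. With fry 0 lists passed, and the smallest adjusted p was 0.254. In the exact sign-flip test of the 6 differences per list, with a smallest possible two-sided p of 0.03125, 0 lists reached p under 0.05 and the smallest p was 0.0625. No list held a gene past the threshold over all genes tested. Adjusted over the list alone, 1 p53 target gene, 1 leukaemia stem cell score gene and 2 stromal and endothelial genes passed, and in each of the remaining lists the count was 0.

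The p53 target genes were higher as a list. Of 27 measured members 21 had a positive log2 fold change and 6 a negative one, with a median of 0.25, and the list mean was higher in 5 of 6 models by 0.28 ± 0.24 (SD, n = 6). With camera the list had an adjusted p of 5.7e-06, and adjusted p = 0.549 with an estimated correlation, the highest of its 12 alternatives, the lowest being 1.8e-08. CDKN1A passed when adjusted over the list alone (adjusted p = 0.0465). The stress-response gene SESN2 had a log2 fold change of 0.58 ± 0.16 (SE) and TNFRSF10B, a death receptor gene, of 0.55 ± 0.18. The list of BCL2 family apoptosis regulators, which shares 3 genes with the p53 list, did not pass (camera adjusted p = 0.223; mean difference 0.14 ± 0.16, higher in 5 of 6 models, and 0.080 with library size alone). In it the proapoptotic genes BBC3 and BAX had log2 fold changes of 0.80 ± 0.29 and 0.58 ± 0.22, and BCL2A1 had 0.70 ± 0.40. BCL2 and MCL1, the antiapoptotic members targeted by inhibitors in AML, stood at -0.16 ± 0.10 and 0.03 ± 0.16; MCL1 stood at -0.069 without model 3, -0.063 without model 5 and -0.043 without the block.

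Monocyte and macrophage genes gave the largest list difference. All 22 measured members had a positive log2 fold change, with a median of 1.03. The list mean was higher by 0.98 ± 1.27 (SD, n = 6), and the spread between models was wide: the differences were 2.52 in model 2, 2.55 in model 3, 0.88 in model 4, 0.40 in model 5, -0.15 in model 6 and -0.30 in model 1. The mean was higher in 4 of 6 models. For this list camera returned an adjusted p of 6.6e-07, and adjusted p = 0.549 with an estimated correlation, the highest of its 12 alternatives, the lowest being 9.4e-12. FCN1, which encodes ficolin-1, averaged 23.2 ± 41.0 CPM after saline and 268 ± 525 CPM after cytarabine, with a log2 fold change of 2.78 ± 0.87 (SE). S100A12, a calcium-binding protein gene of monocytes and granulocytes, had 3.14 ± 1.15, and CSTA, a protease inhibitor gene, 1.53 ± 0.54. No member passed the gene-level test.

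Granule and promyelocyte genes, MHC class II genes and NF-kB and inflammatory genes were also higher as lists, each resting on few models. Of 12 measured granule genes 10 were positive, and the list mean was higher by 0.40 ± 0.61 (SD) in 4 of 6 models. By camera the adjusted p was 0.0398, and adjusted p = 0.662 with an estimated correlation (range over alternatives 3.6e-04 to 0.662). Without model 2, where the list mean differed by 1.51, camera gave 0.323 and the mean was 0.18. The granule genes CTSG, CEBPE and RNASE2 had log2 fold changes of 0.54 ± 0.28, 0.83 ± 0.45 and 1.15 ± 0.62 (SE). All 7 measured MHC class II genes were positive, and the list mean was higher by 0.43 ± 0.89 in 4 of 6 models. In models 4 and 6 this mean lay near the floor, at 0.0705 and 0.0976 in saline and 0.390 and 0.0116 after cytarabine. Model 4 counts among the 4 higher models. The camera adjusted p was 0.0398, and adjusted p = 0.662 with an estimated correlation (range 0.0111 to 0.662). The MHC class II call was lost without model 1 (0.0669), model 3 (0.483), model 4 (0.0556) or model 5 (0.0892), and model 3 alone differed by 2.19. Without model 3 the mean was 0.073. Of 27 measured NF-kB and inflammatory genes 22 were positive, and the list mean was higher by 0.32 ± 0.55 in 4 of 6 models. Camera gave an adjusted p of 3.1e-04, and adjusted p = 0.662 with an estimated correlation (range 2.4e-06 to 0.662). Without model 3, where the list mean differed by 1.41, camera gave 0.198 and the mean was 0.10. In that list NFKB2 had a log2 fold change of 0.52 ± 0.20 (SE), NFKBIA of 0.47 ± 0.19 and the interleukin-1 receptor antagonist gene IL1RN of 1.55 ± 0.61.

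**Figure D3:**
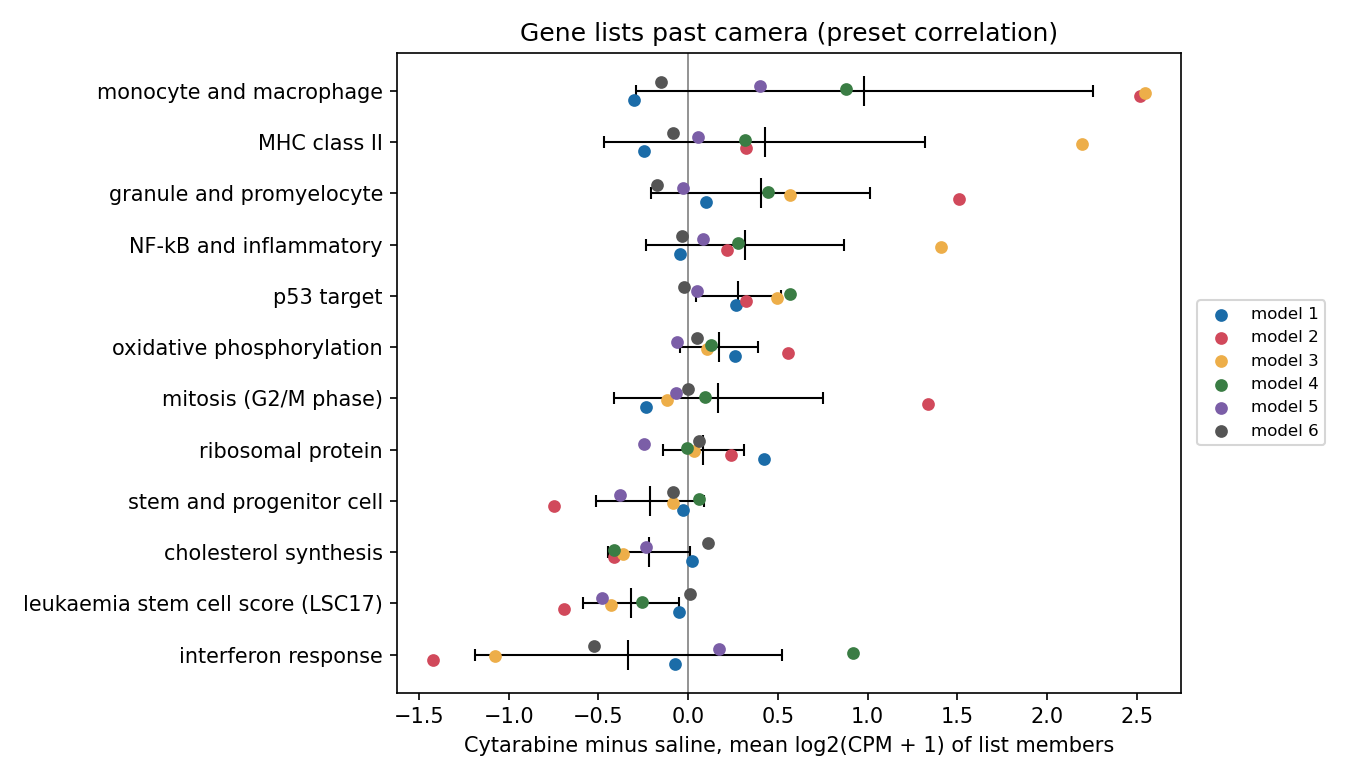
Cytarabine minus saline difference in the mean log2(CPM + 1) of the members of each of the 12 lists past camera with the preset correlation, with a coloured point for each of 6 models and the mean with SD in black. Monocyte and macrophage genes differ by 2.52 in model 2 and 2.55 in model 3, while the differences of models 1 and 6 are -0.30 and -0.15, and no list passed with an estimated correlation.

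Stem cell genes were lower as lists. All 15 measured members of the leukaemia stem cell score (LSC17), a published expression score tied to outcome in AML, had a negative log2 fold change, with a median of -0.32. The unweighted list mean was lower in 5 of 6 models (-0.32 ± 0.27, SD, n = 6), and the score itself was not computed. For this list camera returned an adjusted p of 5.8e-06, and adjusted p = 0.549 with an estimated correlation (range over alternatives 5.0e-07 to 0.549). ARHGAP22 passed when adjusted over the list alone (adjusted p = 0.0304); ADGRG1, a surface receptor gene also known as GPR56, had a log2 fold change of -0.78 ± 0.26 (SE) and NYNRIN of -0.51 ± 0.18. Of 22 stem and progenitor cell genes 18 were negative, and the list mean was lower in 5 of 6 models (-0.21 ± 0.30). By camera the adjusted p was 0.0398, and adjusted p = 0.644 with an estimated correlation (range 0.00113 to 0.644). This call was lost with library size alone as the scaling (0.0973) and without model 2 (0.0939), model 5 (0.238) or model 6 (0.0838), and the mean was -0.10 without model 2. In it ERG and MSI2 were lower in 6 of 6 models, with log2 fold changes of -0.45 ± 0.16 and -0.43 ± 0.15, and MYCN had -0.39 ± 0.17. CD34 had -0.68 ± 0.32 and was lower in 5 of 6 models. Surface antigen genes of AML did not pass as a list (camera adjusted p = 0.934; 10 positive and 12 negative of 22; mean difference 0.10 ± 0.25, higher in 3 of 6 models), and its median was -0.03 while camera and the mean pointed up. The mean was 0.027 without model 3, 0.16 without model 1 and 0.045 with library size alone. CD70, a TNF family ligand gene, had a log2 fold change of 1.45 ± 0.42 and was higher in 6 of 6 models, IL2RA had 1.15 ± 0.36, CD38 had -0.38 ± 0.14 and CD33 had -0.15 ± 0.12. HOX and MEIS genes did not pass either (camera adjusted p = 0.744; mean difference 0.01 ± 0.20, higher in 3 of 6 models). In models 4 and 6 the list mean lay near the floor, at 0.647 and 0.557 in saline and 0.680 and 0.551 after cytarabine. Model 4 counts among the 3 higher models. The mean difference of the HOX and MEIS genes turned to -0.032 without model 1, -0.031 without model 3 and -0.044 with library size alone. It was 0.072 without model 5 and 0.061 with a pseudocount of 0.1. HOXA7 stood at -0.52 ± 0.24, HOXB2 at 0.51 ± 0.38 and PBX3 at 0.11 ± 0.15, the last turning to -0.028 without model 3 and -0.077 without the block. In that list 9 genes were listed at 0 in all 12 paired libraries.

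Genes of the cytarabine pathway did not pass as a list. Of 24 measured genes of cytarabine transport and metabolism 15 were positive and 9 negative (camera adjusted p = 0.320), and the list mean differed by 0.11 ± 0.14 (SD), higher in 5 of 6 models, and by 0.062 without model 2. With library size alone the mean was 0.048 (exact sign-flip p = 0.469). With a pseudocount of 5 the exact sign-flip test of this list gave p = 0.03125, the smallest possible, with an adjusted p of 0.312 and a mean of 0.077 ± 0.096. DCK stood at -0.00 ± 0.09 (SE), a value that turned to 0.000533 with RLE factors and to 0.00574, 0.061 and 0.027 without models 1, 3 and 4. CDA, the deaminase that inactivates cytarabine, had a log2 fold change of 1.45 ± 0.52 and was higher in 5 of 6 models. Its differences in log2(CPM + 1) were 2.71 in model 2 and 1.69 in model 3, against -0.08 to 0.70 in the others. In saline CDA stood near the floor in models 4, 6 and 2 (0, 0.0593 and 0.472 CPM), and the difference in model 4 was 0.084. NT5E and NT5C3A, nucleotidase genes, had 1.40 ± 0.44 and -0.27 ± 0.11. The uptake transporter gene SLC29A1 had 0.20 ± 0.14, NT5C2 -0.27 ± 0.15, RRM2 0.21 ± 0.12 and SAMHD1 0.23 ± 0.40, the last turning to -0.10 without model 4 and to -0.23 without the block. Drug efflux transporter genes did not pass (camera adjusted p = 0.141, and 0.0460 among genes with at least 50 counts in 6 libraries, the lowest of its alternatives, the highest being 0.549; 7 of 9 negative; mean difference -0.15 ± 0.14, lower in 5 of 6 models), with ABCA2 at -0.51 ± 0.20, ABCC4 at -0.52 ± 0.21 and ABCC5 at 0.23 ± 0.12.

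Among metabolic lists, oxidative phosphorylation genes were higher and cholesterol synthesis genes lower. Of 40 measured nuclear-encoded oxidative phosphorylation genes 35 were positive, and the list mean was higher by 0.17 ± 0.22 (SD) in 5 of 6 models. The camera adjusted p was 6.3e-06, and adjusted p = 0.644 with an estimated correlation (range over alternatives 6.4e-07 to 0.644). Without model 2 the mean was 0.096, and with library size alone 0.11. The saline library of model 2 had the lowest mean of the 6 (6.35, against 6.53 to 7.16). NDUFB1, COX6C and COX4I1 had log2 fold changes of 0.49 ± 0.16, 0.38 ± 0.14 and 0.41 ± 0.15 (SE). Of 22 cholesterol synthesis genes 18 were negative, and the list mean was lower in 4 of 6 models (-0.22 ± 0.23). With camera the list had an adjusted p of 8.3e-04, and adjusted p = 0.549 with an estimated correlation (range 4.9e-05 to 0.549). HMGCS1 and SQLE, which encode enzymes of that pathway, had -0.81 ± 0.22 and -0.65 ± 0.25. Of 42 ribosomal protein genes 32 were positive, and the list mean was higher by 0.08 ± 0.23 in 4 of 6 models. Camera gave an adjusted p of 0.0398, and adjusted p = 0.830 with an estimated correlation (range 3.4e-04 to 0.830). That call was lost with library size alone (0.132) and without model 1 (0.824), model 2 (0.122) or model 6 (0.153). The mean was 0.018 with library size alone, 0.016 without model 1, 0.054 without model 2 and 0.15 without model 5. RPL27, RPS19 and RPS16 had 0.21 ± 0.11, 0.31 ± 0.18 and 0.29 ± 0.17. The members of the oxidative phosphorylation and ribosomal protein lists have short transcripts, with median lengths of 714 and 663 bases against 1865 bases over the tested genes with a length. In models 1 to 4 the log2 difference ran against transcript length (Spearman correlation across genes -0.26, -0.23, -0.11 and -0.18), and in models 5 and 6 with it (0.12 and 0.06).

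Fatty acid oxidation genes (camera adjusted p = 0.0797; 15 of 21 positive) and glycolysis and hypoxia genes (0.379; 18 of 28 positive) did not pass as lists. Their means differed by 0.14 ± 0.19 and 0.05 ± 0.11 (SD), each higher in 4 of 6 models. The first was 0.075 without model 2 and 0.078 with library size alone. The second was 0.086 without model 4, 0.035 without model 2 and 0.033 without model 5, and turned to -0.0084 with library size alone. Fatty acid oxidation genes passed without model 1 (0.0169) or model 3 (0.0154), in a range of alternatives up to 0.662. SLC25A20, which carries acylcarnitines into mitochondria, had a log2 fold change of 0.36 ± 0.12 (SE), the fatty acid receptor gene CD36 had 1.81 ± 0.78 and ACADVL 0.28 ± 0.12. CD36 is also in the monocyte and macrophage list, and differed by 4.07 in model 2 and 2.26 in model 3, against -0.53 to 0.76 in the others. PGAM1 had 0.38 ± 0.14, VEGFA 0.58 ± 0.24 and P4HA1 -0.32 ± 0.15. Genes of MYC-driven ribosome biogenesis did not pass (0.744; 12 positive and 13 negative; mean difference -0.01 ± 0.19, lower in 3 of 6 models). Their mean turned to 0.024 without model 3, 0.0017 without model 4 and 0.036 without model 5, and was -0.063 without model 2 and -0.076 with library size alone. WDR43 stood at -0.28 ± 0.12, DDX21 at -0.37 ± 0.16, RRP12 at 0.34 ± 0.19 and MYC itself at -0.17 ± 0.21. No mitochondrially encoded gene was in the table, so that list was not tested.

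Mitosis genes differed in model 2 more than in the others. Of 41 mitosis (G2/M phase) genes 35 were positive, and the list mean was higher by 0.17 ± 0.58 (SD), though in 2 of 6 models. By camera the adjusted p was 0.00992, and adjusted p = 0.814 with an estimated correlation (range over alternatives 1.0e-05 to 0.814). The list mean was 1.33 higher after cytarabine in model 2 and between -0.23 and 0.09 in the other models. In saline the list mean was 5.06 in model 2 against 6.17 to 6.44 in models 1 and 3 to 6, and the cytarabine library of model 2 (6.398) lay within the range of the other cytarabine libraries (5.94 to 6.45). With 1 library each, an unusual saline library and a rise after cytarabine could not be separated. Without model 2 the direction turned (adjusted p = 0.0766) and the mean was -0.065. With library size alone the mean was 0.10. CKS2, BIRC5 and CENPA had log2 fold changes of 0.31 ± 0.13, 0.40 ± 0.25 and 0.42 ± 0.27 (SE), and the proliferation marker gene MKI67 had 0.40 ± 0.30. DNA replication genes did not pass (0.624; 22 positive and 15 negative; mean difference 0.03 ± 0.19, higher in 4 of 6 models). Their mean turned to -0.029 without model 2 and -0.038 with library size alone, and was 0.076 without model 3, 0.061 without model 5, 0.0070 without model 4 and 0.016 without model 6. POLA1 stood at -0.22 ± 0.11, E2F1 at 0.27 ± 0.14 and CCNE1 at 0.43 ± 0.23. DNA damage signalling and repair genes did not pass (0.112; 12 positive and 21 negative; mean difference -0.08 ± 0.15, lower in 4 of 6 models). Their mean was -0.050 without model 1, -0.048 without model 3 and -0.15 with library size alone. MSH6 stood at -0.54 ± 0.21, PALB2 at -0.34 ± 0.14 and TP53BP1 at -0.33 ± 0.16. The replication list passed without model 3 (0.0346, range 0.0346 to 0.965), and the repair list without model 2 (0.0285) or model 6 (0.0395, range 0.0285 to 0.770).

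Interferon response genes were lower as a list but went both ways between models. Of 21 measured genes 20 were negative, and the list mean was lower in 4 of 6 models (-0.33 ± 0.86, SD). The camera adjusted p was 0.00567, and adjusted p = 0.740 with an estimated correlation (range over alternatives 5.0e-11 to 0.740). The list mean differed by -1.42 in model 2 and -1.07 in model 3, but by 0.92 in model 4. The call was lost without model 2 (0.218), model 3 (0.189) or model 6 (0.0794). The mean was -0.12 without model 2, -0.18 without model 3 and -0.58 without model 4. MX2, USP18 and CMPK2 had log2 fold changes of -0.46 ± 0.21, -0.50 ± 0.26 and -0.51 ± 0.29 (SE). Unfolded protein and integrated stress response genes did not pass (0.223, and 0.0440 without model 3, range 0.0440 to 0.677; 15 of 23 positive; mean difference 0.08 ± 0.20, higher in 5 of 6 models). Their mean was 0.031 without model 2, 0.14 without model 3, 0.031 without model 6 and 0.015 with library size alone. CHAC1 stood at -0.98 ± 0.29 and SDF2L1 at 0.72 ± 0.24. Immediate early and heat shock genes, which can report on sample handling, did not pass (0.210, and 0.00445 without model 2, range 0.00445 to 0.981; 13 positive and 12 negative; mean difference 0.09 ± 0.28, higher in 4 of 6 models). Their mean turned to -0.014 without model 3, and was 0.15 without model 2 and 0.019 with library size alone. The saline library of model 2 had the highest mean of the 6 (9.83, against 7.56 to 9.25). KLF2 had 0.48 ± 0.19, ZFP36 0.52 ± 0.22 and BAG3 0.35 ± 0.15.

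The stromal and endothelial, B and plasma, T and NK, erythroid, megakaryocyte and adhesion lists did not pass camera with its preset correlation. The monocyte, granule and MHC class II lists above did, but with an estimated correlation, fry or the sign-flip test 0 lists passed. How mouse reads were treated is not given, so the lists of this paragraph were not read as amounts of such cells in the marrow. Stromal and endothelial genes did not pass camera (adjusted p = 0.112, and 0.0312 among genes with at least 50 counts in 6 libraries, range 0.0312 to 0.858; 9 of 12 negative; mean difference -0.18 ± 0.14, lower in 5 of 6 models), but PDGFRB and COL6A1, lower in 6 of 6 models, passed when adjusted over the list alone (adjusted p = 0.0348 for both). Their log2 fold changes were -0.69 ± 0.18 and -0.87 ± 0.24 (SE), and CDH5 had -1.51 ± 0.64. B and plasma cell genes (0.0894, and 0.0465 without model 1 or 0.00330 without model 2, range 0.00330 to 0.765; mean difference -0.12 ± 0.21, lower in 4 of 6 models, 4 positive and 4 negative of 8 with a median of -0.09, -0.038 without model 3 and -0.22 with a pseudocount of 0.1) included MZB1 at -0.69 ± 0.23, VPREB1 at -0.86 ± 0.32 and CD22 at -0.75 ± 0.32. T and NK cell genes (0.744; 7 positive and 7 negative; mean difference -0.00 ± 0.31, lower in 3 of 6 models, from -0.11 without model 4 to 0.066 without model 6, and above 0 without model 3 or 5 too) included IL7R at -0.91 ± 0.40, NKG7 at 0.81 ± 0.48 and CD3E at -0.46 ± 0.31. Erythroid genes (0.862; 4 positive and 4 negative; mean difference 0.09 ± 0.25, higher in 5 of 6 models, 0.023 without model 2, 0.18 without model 5, 0.026 with a pseudocount of 0.1 and 0.056 with library size alone) included EPOR at 0.64 ± 0.34, GATA1 at 0.85 ± 0.68 and TFRC at -0.25 ± 0.21, and camera pointed down while the median and mean were above 0. Megakaryocyte and platelet genes (0.819; 2 positive and 6 negative; mean difference 0.03 ± 0.32, higher in 3 of 6 models, turning to -0.056 without model 3, -0.034 without model 4 and -0.018 with library size alone, and 0.10 without model 2) included GP9 at 0.83 ± 0.32 and PLEK at 0.47 ± 0.19, and camera and the mean pointed up while the median was -0.10. Adhesion and bone marrow homing genes (0.771; 7 positive and 11 negative; mean difference -0.01 ± 0.16, lower in 4 of 6 models, turning to 0.037 without model 1 and 0.0025 without model 6, and -0.076 with library size alone) included ANXA2 at 1.07 ± 0.37, ITGA4 at -0.54 ± 0.21, ITGB2 at 0.49 ± 0.20 and CXCR4, the marrow homing receptor gene, at 0.26 ± 0.22.

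The last comparison set the differences of the models against each other. Over the 15 pairs of models the median Pearson correlation of the log2 differences across genes was 0.02, ranging from -0.24 to 0.50, and 7 pairs were below 0. The highest value belonged to models 2 and 3, and the Spearman values over the same pairs ranged from -0.24 to 0.47 with a median of 0.02. Among genes with over 1000 counts in both libraries of a model, the SD of the log2 difference was between 3.97 times (model 6) and 13.8 times (model 2) what counting error alone gives. With 1 library per model and treatment, a difference within 1 model has no replicate check.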

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

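Chosen after the results were seen were the tests of RNA handling, of ribosomal protein genes among the genes listed at 0, and of transcript length for the ribosomal protein list, as well as the naming of FCGBP. For RNA handling a bound of 2 SE replaced a bound of 0 after the means were known. The other tests in this part were stated before their results were seen.

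Model 2 stood apart from the other 5 models in 9 sets of values searched for a single distant value, and model 3 in 3. For sets picked without regard to their values, chance alone gives such a value in about 1 in 20, or 8.3 of the sets searched here. Some genes searched, FCGBP among them, were named for being among the largest differences of 1 model. Others were named for a small p, so the 8.3 is no valid expectation for these sets. After cytarabine CD34 differed by -2.67 (log2) in model 2, against -0.52 to 0.03 in the others, ERG by -1.34 against -0.45 to -0.15, and MSI2 by -1.27 against -0.40 to -0.07. The cycling genes MKI67, BIRC5 and CENPA differed in model 2 by 2.18, 1.90 and 2.0, against upper values of 0.70, 0.27 and 0.32 in the others, and the G2/M phase list by 1.33 against -0.23 to 0.09. In that list the saline library of model 2 itself stood low, at 5.06 against 6.17 to 6.44 in the other models. In model 2 CCL23 differed by 2.68 against -0.22 to 0.76, and LILRB1 by -0.97 against -0.10 to 0.31. In model 3 the NF-kB and inflammatory list differed by 1.41 against -0.04 to 0.28, the MHC class II list by 2.19 against -0.24 to 0.32, and FCGBP by 6.88 against -0.41 to 0.71.

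Monocyte and macrophage genes were higher after cytarabine, most in models 2 and 3. Scaling argued against itself as the cause, since the mean difference under other factors kept at least 0.944 of its TMM value. RNA handling stays open: over 25 immediate early and heat shock genes the mean difference was -0.26 ± 0.14 (SE over genes) in model 2, less than 2 SE below 0 and with the highest saline mean of the 6 models (9.83), and 0.58 ± 0.12 in model 3, above the 0.5 that handling would need. Reads from mouse marrow cells counted as human stay open too: 5 monocyte genes with no mouse counterpart had a median difference of 0.57 in models 2 and 3, between the bounds set beforehand, with MNDA at 3.86 and 3.02 but CXCL8 at -0.09 and 1.83, CCL23 at 2.68 and 0.76, LILRB1 at -0.97 and 0.31 and CD58 at 0.18 and 0.38. A shift of the leukaemia cells towards a monocytic state may also contribute, and was not tested apart from this.

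In the libraries of models 7 and 8, outside the paired comparison, 700 genes had over 100 counts in both but 0 in all 12 paired libraries, of 9572 genes over 100 in both. They held 6.52% and 6.21% of the counts of those libraries, and 8 genes went the other way. Silence of these genes in the paired models is argued against by 7 ribosomal protein genes among them, and loss of reads shared with pseudogenes by a share with a named pseudogene 0.860 times that of expression-matched genes. Most exonic bases lay in exons of other genes in 15.6% of them against 1.86% of matched genes, a ratio of 8.38, so dropped reads in overlapping genes may account for part, while most of the 700 have no such overlap. Apart from silence, no biological explanation was tested.

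Oxidative phosphorylation and ribosomal protein genes, both with short transcripts, were higher as lists. The length test was prompted by long genes standing among the largest differences of model 1. After subtracting the mean difference of the 20 genes nearest in length, the ribosomal protein list kept -0.0168 of its difference (from 0.08 to -0.00 ± 0.19, SD), so a length trend may account for it. The oxidative phosphorylation list kept 0.722 (from 0.17 to 0.12 ± 0.18), between the bounds set beforehand, so length stays open there. The neighbours in length can include members of the same lists, and a biological change in these genes was not tested separately.

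For the count of genes past the threshold the splits and swaps decide nothing, since no count can fall below the real count of 0. All 100 splits of the 12 libraries drawn from 462, the real one included, gave at least the 0 genes of the real one. The highest other count was 954, in splits that part only 2 models. With the model as a block, such splits compare libraries within those 2 models alone, so different splits can repeat the same fit. All 32 ways of assigning treatment within models, the real one included, gave at least 0 genes (highest other 0). Chance could not be excluded for the count of lists: of the 32 assignments, the real one included, 10 gave at least the 12 lists of the real labels, the highest other count being 15.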

How the results depend on the processing

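One alternative, filterByExpr with the paired design, was chosen after seeing the data and also gave 0 genes. The DESeq2 test gave 5 genes (2 higher, 3 lower) where edgeR gave 0, and the cause was not tested; every other setting, leave-one-out included (0 to 0), gave 0. Without the replicate block 0 genes and 7 lists passed, and the missing block changed no other call beyond those named here and in the list results. With an estimated correlation 0 lists passed and with fry 0; without single models 10 to 12 passed. The G2/M list turned down without model 2 (adjusted p = 0.0766; range without single models 4.9e-05 to 0.0766). Of 360 list tests under other settings 302 stayed on the same side, 46 no longer passed, 11 newly passed and 1 reversed. The exact sign-flip count, 0, became 3 with a pseudocount of 5 (cytarabine transport, stem and progenitor, stromal and endothelial; adjusted p = 0.312 each) and 2 with library size alone (stem cell score, stromal and endothelial; 0.469 each); without a model it has too few pairs to pass. Of 1025 values for 115 named genes 1013 kept their sign. DCK turned to 0.000491 with DESeq2, 0.000533 with RLE factors, and ranged from -0.054 to 0.061 without single models. Without the block SAMHD1 turned to -0.23, MCL1 to -0.043 and PBX3 to -0.077. Without single models SAMHD1 ranged from -0.10 to 0.51, MCL1 from -0.069 to 0.17 and PBX3 from -0.028 to 0.19. Over the 500 most variable genes the own-pair correlation fell to 0.950 and that with other models to 0.132. The median correlation between models ranged from -0.03 to 0.15 without single models. The cause of these changes was not tested. Median log2 fold changes over all genes lay between -0.07 (library size alone) and -0.00 (RLE factors).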

Other observations

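The test of differing responses was chosen after the result was seen, as were the genes named in the next paragraph, which are among the largest differences of a model and have no replicate check. The tests of depth and of exchanged libraries were stated before their results were seen.

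Some of the largest differences of a model were shared with others, and some went both ways. In models 1 to 6 in turn LYZ, the lysozyme gene, differed by -0.36, 4.34, 3.44, 4.08, 0.37 and -0.28, S100A8 by -0.43, 6.20, 4.34, 1.33, 0.56 and 0, and S100A12 by -0.41, 4.82, 4.67, 0.24, 1.28 and 0. S100A9, a calcium-binding protein gene of myeloid cells, differed by -0.996, 6.28, 3.74, 1.52, 0.85 and -0.31, and CD14, the monocyte lipopolysaccharide co-receptor gene, by -0.82, 3.05, 5.05, -0.33, 0.39 and 0.78. MPO, the myeloperoxidase gene, differed by -0.41, 3.13, -2.03, 2.06, -0.21 and -0.28. SCD, a fatty acid desaturase gene, differed by 0.21, -0.94, -1.40, -2.54, -0.30 and 0.62. The interferon-stimulated genes IFI44L and ISG15 differed by 0.30, -3.35, -2.13, 2.13, 0.56 and -1.07, and by 0.59, -0.59, -1.02, 1.46, -0.31 and -1.17. ERAP1 differed by -1.29, -2.30, -1.26, -0.28, 0.24 and 0.42. The long genes CLTC and DYNC1H1 differed by -1.72, -1.19, -0.99, -0.20, 0.38 and 0.44, and by -1.52, -1.24, -0.67, -0.89, 0.37 and 0.55. FCGBP went from 4.996 to 707 CPM in model 3.

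Why no gene passed the edgeR test although single models differed was put to 3 tests. An exchange of libraries between models 4 and 6 was argued against, since 4 of their 4 libraries matched their own partner best. For sequencing depth, libraries of separate samples exceed counting error at any depth, so passing the bound of 3 times set beforehand excluded nothing. Among genes with over 1000 counts the SD of the log2 difference was 3.97 to 13.8 times the counting error in 6 of 6 models. Counting error was thus a small part of the spread of these genes, which argues against depth for them. For genes with fewer counts depth stays open. Differing responses between models may account for it, with a median correlation across genes of 0.0213 between the differences of 2 models. With 1 library per model and treatment this cannot be separated from variation between single animals or libraries. Of the 32 ways of assigning treatment within models, the real one included, 5 gave at least the 918 genes at an unadjusted p under 0.05 of the real labels, and the highest other count was 2185.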
